A study of Mus musculus with 12 samples.

How the data were processed

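The data were 12 RNA-seq libraries from tumours grown from wild-type B16F10 cells, a pigmented mouse melanoma line, implanted in the skin of both legs of male mice aged 8 to 12 weeks on day 0. All hosts carried a Cre recombinase that tamoxifen activates, expressed from the Rosa26 locus. The 6 Ctrl libraries came from hosts with 1 floxed Trex1 copy and the 6 iKO libraries from hosts with both copies floxed, per the labels. Hosts received 1 mg of tamoxifen a day for 3 days from day 5, and tumours were taken on day 14, per the labels' protocols. The tumours were digested with enzymes and sorted before RNA was extracted. The cell type label describes cells negative for both CD45, a leukocyte marker, and CD31, an endothelial marker, while the protocol text says negative for 1 or the other. The labels also call the library source single cell, and the series text speaks of infiltrating immune cells, whereas the table held 1 column per tumour library. They were analysed here as bulk libraries of sorted tumour tissue. The labels give 1 sequencing batch for all 12 libraries. They do not tie libraries to mice, and a mouse with a tumour on each leg could have given more than 1 library. The p-values therefore measure only the spread between these libraries, which may be smaller than that between mice.

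The deposited values were counts, whole numbers of reads per Ensembl gene that the authors had not divided by gene length or library size. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, their versions and the strand setting of the counting are not given in the sources used here. Messenger RNA was selected with poly-T beads and the libraries did not keep strand, per the labels' protocols. Reads from overlapping genes on opposite strands could therefore not be told apart. Of the 54532 genes of the deposited table, 54409 were found in GENCODE M21 (GRCm38, the assembly that mm10 names). Of these, 53499 (98.3%) had the same start and end in both. Exon overlaps between genes were taken from the GENCODE annotation. Coordinates are those of the deposited table.

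Counts summed to between 29.8 and 45.8 M per library. A count of 0 in a library allows up to 3 counts, or 0.0655 to 0.101 CPM (counts over the library total, times 1e6) depending on the library, and such floors and count intervals (95%) cover counting error only. The 16164 genes kept by edgeR's filter (minimum count 10, minimum total 15) held 99.9% of all counts. No pair of libraries of 1 group was alike within sampling noise: the chi-square per degree of freedom over genes with at least 20 counts in the pair was 7.47 or more in every same-group pair, so each library was counted as 1 replicate.

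The groups were compared with edgeR 4.0.16 (quasi-likelihood test, robust, TMM normalization, group as the only term, all 12 libraries) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. CPM are TMM-scaled, and mean ± SD over the 6 libraries of a group are given with them. The SE of a log2 fold change is approximate: its absolute value over the square root of the F statistic of the quasi-likelihood test. Gene lists were tested with limma 3.58.1: camera with a correlation preset at 0.01, camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. Camera and fry ran on log2 CPM with a prior count of 2, and p-values were adjusted over the lists. A list score is the mean log2 CPM of its measured members in a library. Scores were compared by an exact two-sided permutation test over all 924 assignments of the libraries, whose smallest p is 0.00216.

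The design, the test, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made later. The 39 lists hold 628 genes, of which 570 passed the filter and 19 stand in more than 1 list; 38 lists had at least 3 measured members. Named genes were Trex1 and the sort markers Ptprc (CD45) and Pecam1 (CD31). To these were added the 8 protein-coding genes with the largest rise and the 8 with the largest fall among those past the threshold with at least 1 CPM in the higher group, and for each list up to 4 members with the smallest p among those past the threshold. Where no member passed, the 2 members with the highest mean CPM were given as values. Some genes that met this rule are not reported here and were not replaced, and values of single genes and counts of named genes leave them out. Genes outside this rule are said to have been named after their values were seen.

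The tests were run on simulated counts drawn from the real means and library sizes, with 200 of 16164 genes changed, for iKO against Ctrl. The changed genes were drawn from those with a mean of at least 1 CPM and went up and down about equally. The edgeR test recovered 46.3% of 67 genes changed 1.5-fold, 65.7% of 67 changed 2-fold and 84.8% of 66 changed 4-fold, and 5.07% of its calls were false. In the real data 25.0% of tested genes rose and 21.4% fell, and 1034 that rose had a Ctrl mean under 1 CPM. The simulated shares therefore need not hold there. False calls were 3.68% with limma voom and 19.0% with the DESeq2 Wald test, whose counts of calls are to be read with that share in mind. None of 30 simulated lists without a change was called by any list test. Genes were simulated independently, whereas the estimated correlation in the real lists was, for example, 0.51 (type I interferon) and 0.89 (macrophages and monocytes). The simulation therefore does not show how often the list tests call falsely, or miss a change, in lists whose genes move together. A raised list was called by camera both ways and by fry, while the score permutation gave it an adjusted p of 0.0671, since a single list among so many cannot pass at its smallest p.

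The alternatives were DESeq2 size factors, total counts without a composition factor, the DESeq2 1.42.0 Wald test, limma voom with and without sample weights, no filter or CPM of at least 1 in at least 6 libraries, protein-coding genes only, an absolute log2 fold change of at least 1, the replicate number as a block, the leukocyte or the fibroblast list score as a covariate, a prior count of 0.5, standardised scores and leaving out each library. Added after the data were seen were runs without iKO 2 and 3, without iKO 2 and 5, and with counts thinned to the smallest library. The real split of the 12 libraries was also compared with other splits, 100 in all with the real one.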

Results

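RNA was measured in tumours that grew for 14 days from wild-type B16F10 melanoma cells in the skin of mice, after sorting against leukocytes and endothelial cells. Hosts of the 6 Ctrl libraries kept 1 intact copy of Trex1, which encodes a DNA exonuclease of the cytosol, whereas hosts of the 6 iKO libraries had both copies floxed, and all received tamoxifen. The comparison asks how loss of Trex1 in the host, with the implanted cells left wild type, changes gene expression in the sorted tumour. Ctrl libraries 1 to 6 held 45.8, 42.0, 37.7, 34.3, 36.4 and 44.9 M deposited counts, and iKO libraries 1 to 6 held 30.0, 31.4, 35.3, 29.8, 35.1 and 35.5 M. The mean was 40.2 ± 4.72 M in Ctrl and 32.8 ± 2.75 M in iKO (SD, n = 6 each), a difference larger than the spread between libraries (exact permutation test, adjusted p = 0.0180). More genes had a count in iKO, 21862.3 ± 477 against 20783.5 ± 322 (SD, n = 6, exact permutation test, adjusted p = 0.0162), despite the lower totals. Mitochondrial transcripts took 1.21% of counts in Ctrl and 1.56% in iKO, a difference within the spread (exact permutation test, adjusted p = 0.0785).

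Trex1 (ENSMUSG00000049734, mm10 chromosome 9, 109057933 to 109059734) had 0 counts in each of the 12 libraries, so its level could not be compared and the genotype labels could not be checked from it. All of its 1147 annotated exon bases (100%) lie within Atrip, which encodes a partner of the ATR kinase. Among 176 protein-coding genes whose exons lie fully within another gene's exons, 173 (98.3%) also had 0 counts in all libraries, against 3737 of 15386 genes without overlap (24.29%). Atrip itself had 6090 counts in Ctrl and 4295 in iKO, with a log2 fold change of -0.18 (edgeR, adjusted p = 0.121), and reads from Trex1 cannot be told apart from its own.

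Gene expression differed widely between the groups: 4037 of 16164 tested genes (25.0%) rose in iKO and 3464 (21.4%) fell. Rises were larger than falls, with a median log2 fold change of 0.90 among genes that rose and -0.37 among those that fell, and 1891 rises but only 95 falls reached an absolute log2 fold change of 1. Among the 8 largest rises, Ctla4, an inhibitory receptor of T cells, rose from 0.0168 ± 0.0266 to 10.1 ± 5.45 CPM (SD, n = 6), a log2 fold change of 8.98 ± 0.85 (SE), and Tlr9, an endosomal DNA sensor, from 0.0797 ± 0.118 to 27.1 ± 13.9 CPM (8.43 ± 0.97). Cd244a, a receptor of natural killer and T cells, rose by 8.04 ± 1.00 and Cd8b1, a chain of the CD8 co-receptor, by 7.76 ± 1.09. Sh2d1a and Crtam, both expressed by lymphocytes, had 0 counts in Ctrl against 220 and 208 in iKO, at least 89.8-fold and 84.9-fold higher with 3 counts as the floor over the group. Ipcef1 went from 2 to 863 counts, a ratio of 528 (95% counting interval 146 to 4368), and Ms4a8a from 2 to 677, a ratio of 414 (114 to 3428). Of Sh2d1a exon bases 26.6% are shared with Tenm1, and the values of Cd8b1, Tlr9, Ctla4 and Cd244a rest partly on single Ctrl libraries. The log2 fold change was 9.52 for Tlr9 without Ctrl 5 and 8.90 for Cd244a without Ctrl 4, where Ctla4 had 2 Ctrl counts against 1953 in iKO, a ratio of 1025 (95% counting interval 283 to 8469). All Ctrl counts of Cd8b1 (12), Ipcef1 (2) and Ms4a8a (2) were in Ctrl 5. Without it these genes were at least 786-fold, 299-fold and 234.5-fold higher, with the same floor over the 5 other Ctrl libraries.

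The largest falls were smaller. Gkn3, a gastrokine, fell from 902 counts in Ctrl to 17 in iKO (log2 fold change -5.36 ± 0.53) and Tex19.1, a gene of the germ line, from 270 to 14 (-3.87 ± 0.69, and -4.80 without iKO 1). Fgf21, a metabolic hormone, changed by -2.33 ± 0.53, Nxf3, a nuclear export factor, by -2.26 ± 0.78, and Col9a1, a cartilage collagen, by -2.05 ± 0.25. Bcan, a proteoglycan, Rlbp1, a retinoid carrier, and Mmp15, a membrane-bound matrix protease, changed by -1.62 ± 0.58, -1.58 ± 0.24 and -1.55 ± 0.22. The call of Nxf3 (edgeR, adjusted p = 0.0288) was lost without Ctrl 1 (0.0637), Ctrl 2 (0.0579), Ctrl 6 (0.0501), iKO 1 (0.0501) or iKO 5 (0.0625), and its change was -3.27 without iKO 3. That of Bcan (0.0342) was lost without any 1 of Ctrl 1 to 6 or iKO 2, 4 or 6, at adjusted p from 0.0506 to 0.0718.

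The first principal component of log2 CPM held 70.4% of the variance and separated the groups, but Ctrl 5 (-17.1) and iKO 1 (-0.973) lay between the other Ctrl libraries (-91.6 to -74.4) and the other iKO libraries (76.3 to 104). In 3699 genes (22.9%) the 2 groups did not overlap, against 0.216% by chance. With the leukocyte score as covariate, 1095 genes were higher and 1179 lower, of which 815 and 1009 had the same call without it.

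Transcripts of both markers used in the sort were higher in iKO. Ptprc, which encodes CD45 (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708), rose from 3.10 ± 6.12 to 191 ± 108 CPM (SD, n = 6), a log2 fold change of 5.98 ± 1.20 (edgeR, adjusted p = 0.00244). Pecam1, which encodes CD31, rose from 4.18 ± 0.705 to 10.9 ± 3.72 CPM (1.38 ± 0.25, adjusted p = 0.000565). Ptprc was at 15.6 CPM in Ctrl 5 and between 0.158 and 1.54 CPM in the other Ctrl libraries, and at 17.4 CPM in iKO 1 and between 159 and 345 CPM in the other iKO libraries. Its log2 fold change was 8.35 without Ctrl 5. Ptprc is a member of the leukocyte list, so its fall to 0.54 with the leukocyte score as covariate follows from that model, whereas Pecam1, which is not, went to -0.023, both without a call.

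Sex-linked transcripts, looked at after the data were seen, differed among the iKO libraries although the labels give male mice throughout. Xist, the RNA that silences an X chromosome in female cells, was at 219 CPM in iKO 2, 117 in iKO 3, 8.39 in iKO 4 and 1.18 in iKO 5, and at 0.501 CPM or less in each other library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 44 counts in iKO 2 and 0 in iKO 3, which allows up to 0.0850 CPM there, against 239 in iKO 1 and 1298 to 1513 in iKO 4, 5 and 6. In Ctrl they summed to 107 to 254 counts. Without iKO replicates 2 and 3, an omission chosen after this was seen, 3570 genes were higher and 2965 lower.

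**Figure D1:**
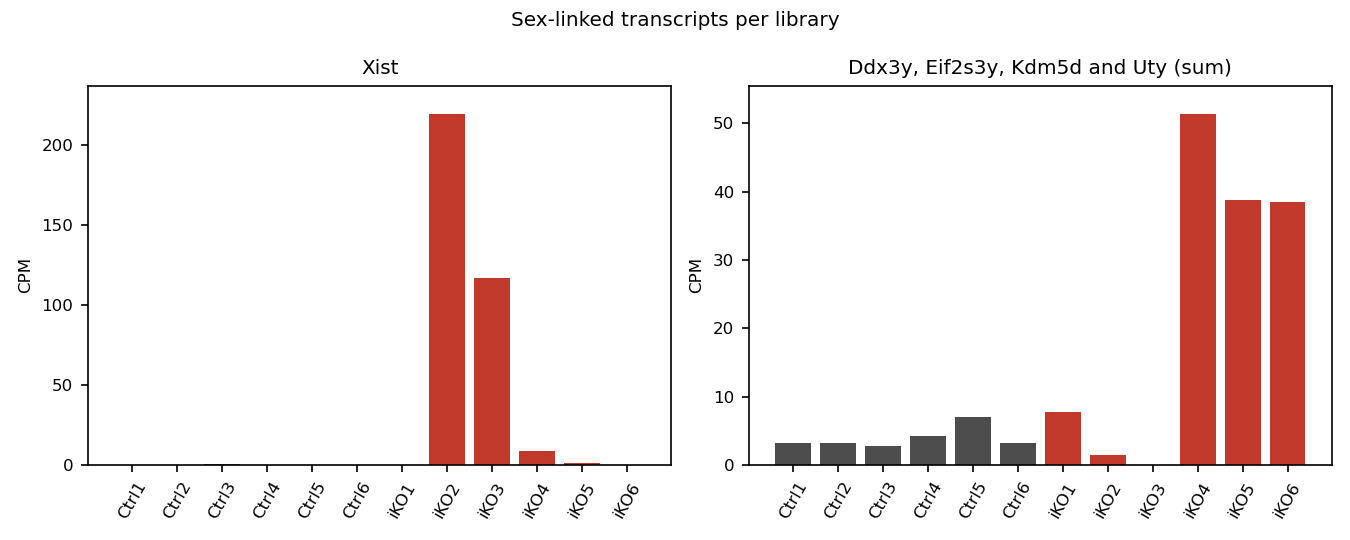
Bars give Xist (CPM) and the summed CPM of Ddx3y, Eif2s3y, Kdm5d and Uty in each of the 12 libraries. Xist stands at 219 CPM in iKO 2 and 117 CPM in iKO 3, where the 4 Y-linked genes sum to 44 and 0 counts.

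Interferon-stimulated genes rose together in iKO. All 34 measured genes of the type I interferon list rose, by a median log2 fold change of 2.03 (4.09-fold). Rsad2 (viperin), an antiviral enzyme, went from 97.3 ± 3.25 to 372 ± 35.0 CPM (SD, n = 6, log2 fold change 1.94 ± 0.07), the RNA sensors Ddx58 (RIG-I) and Ifih1 (MDA5) rose by 1.57 and 1.98, and Parp14, an ADP-ribosyltransferase, by 2.64. All 26 measured genes of the interferon gamma list rose, by a median of 2.37, among them the guanylate-binding proteins Gbp2 (2.32), Gbp3 (2.20) and Gbp7 (2.21) and the immunity-related GTPase Irgm1 (1.75). In both lists the counts adjusted over the list alone were also 34 and 26. The camera adjusted p was 4.98e-32 for type I interferon and 4.12e-23 for interferon gamma, and for both lists adjusted p = 0.262 with an estimated correlation.

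Antigen presentation on MHC class I followed the same direction. Of 23 genes 20 rose and 3 fell, also when adjusted over the list alone, with a median of 1.86 (camera adjusted p = 9.78e-13; adjusted p = 0.262 with an estimated correlation). The peptide transporters Tap1 and Tap2 rose by 2.33 and 2.11, the trimming peptidase Erap1 by 1.46, and B2m, the light chain of MHC class I, from 862 ± 80.8 to 2294 ± 237 CPM (SD, n = 6). The 3 that fell, named after their values were seen, were the general chaperones of the endoplasmic reticulum Calr (-0.27), Canx (-0.34) and Pdia3 (-0.27). Among 22 nucleic acid sensing genes 16 rose and 3 fell, also adjusted over the list alone, with a median of 0.93 (camera adjusted p = 8.49e-07; adjusted p = 0.262 with an estimated correlation). Ifi203, of the family of DNA-binding interferon-inducible proteins, rose by 2.97 and Adar, which edits double-stranded RNA, by 1.06. The 3 that fell, named after their values were seen, encode the subunits of ribonuclease H2, Rnaseh2a (-0.30), Rnaseh2b (-0.42) and Rnaseh2c (-0.51). Of 19 genes of inflammatory and programmed cell death 16 rose, 17 adjusted over the list alone, with a median of 1.01 (camera adjusted p = 9.00e-09; adjusted p = 0.262 with an estimated correlation). They included Casp4 (1.94), an inflammatory caspase, Zbp1 (2.99), a sensor of Z-form nucleic acid, Tnfsf10 (3.13), a death ligand, and Gsdmd (2.25), which forms pores in the membrane.

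The leukocyte list score rose beside these 5 lists, from 1.47 ± 1.55 to 6.45 ± 1.18 mean log2 CPM (SD, n = 6, exact permutation test, adjusted p = 0.00609), a difference of 4.97, and 5.58 without Ctrl 5. It was 4.41 in Ctrl 5 and 4.11 in iKO 1, whose type I interferon scores were 4.67 and 6.18, while the other Ctrl libraries had interferon scores of 4.39 to 4.45 and the other iKO libraries of 6.70 to 6.95. With the leukocyte score as covariate, 33 of the 34 type I interferon genes were still higher (median log2 fold change 1.601), and so were 19 of the 26 interferon gamma genes (2.07) and 16 of the 23 MHC class I genes (1.32). The numbers were lower for nucleic acid sensing (7 higher and 3 lower, median 0.38) and cell death (7 higher, 0.42). This adjustment rests mainly on Ctrl 5 and iKO 1, the libraries whose leukocyte scores lay between the others. Between the leukocyte and type I interferon scores Pearson r was 0.92 within Ctrl and 0.86 within iKO (exact permutation test, adjusted p = 0.196 and 0.240). Without the 2 libraries farthest from the median leukocyte score r was 0.062 and -0.44. Neither correlation over all 6 libraries of a group passed the threshold, and Spearman rho was 0.49 within Ctrl and 0.029 within iKO. The Pearson correlations of the leukocyte score with the cell cycle and pigment cell scores did not pass in either group either (exact permutation test, adjusted p of 0.240 or more).

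**Figure D2:**
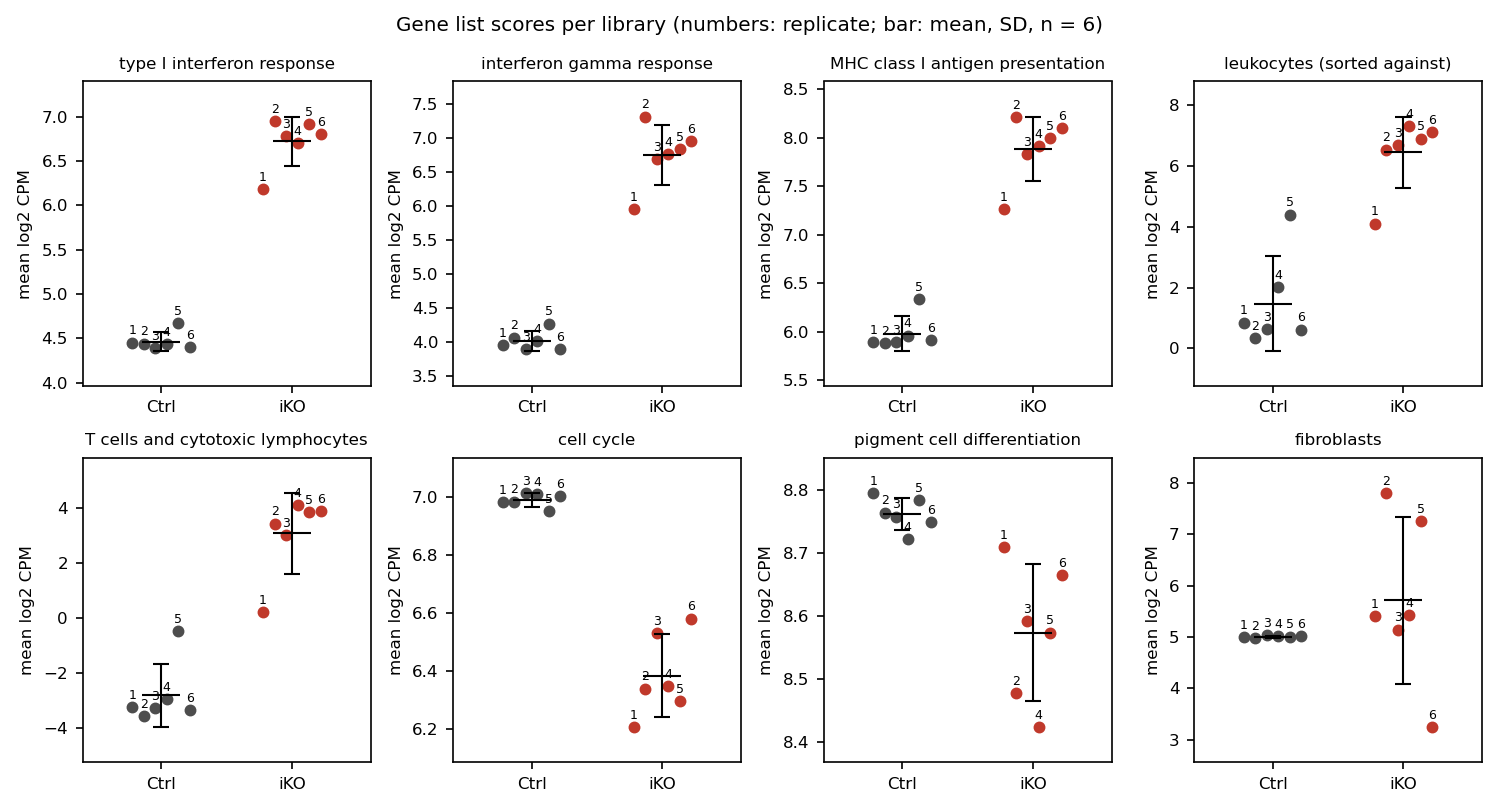
Each point is a library, numbered by replicate, and gives its mean log2 CPM over the members of a list; bars are the mean and whiskers the SD of 6 libraries per group. The type I interferon scores lie between 4.39 and 4.67 in Ctrl and between 6.18 and 6.95 in iKO.

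**Figure D3:**
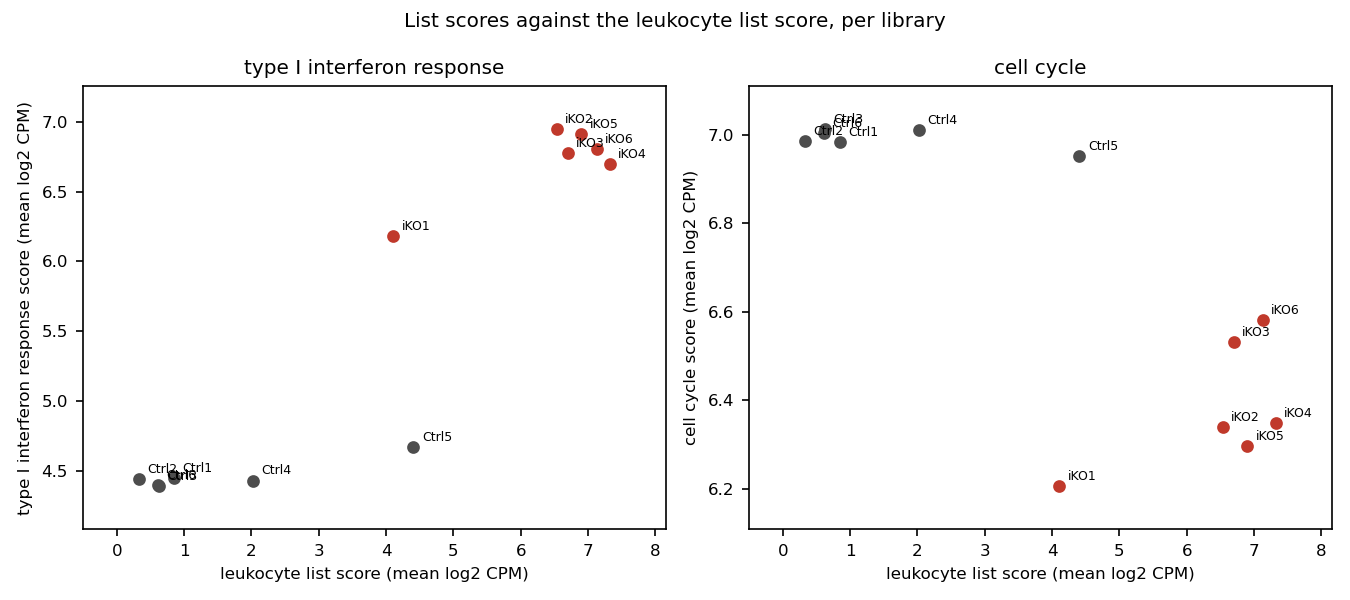
The type I interferon score and the cell cycle score (mean log2 CPM) of each library are plotted against its leukocyte score. Ctrl 5 and iKO 1 have leukocyte scores of 4.41 and 4.11 and interferon scores of 4.67 and 6.18.

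Although the cells were sorted as negative for CD45, transcripts of leukocytes were higher in iKO. Of 10 leukocyte genes 9 rose, also adjusted over the list alone, with a median of 5.04, among them the GTPase Rac2 (5.71), the actin bundler Lcp1 (3.23) and the phosphatase Ptpn6 (1.38); Arhgdib, named after its value was seen, had a log2 fold change of -0.023 (edgeR, adjusted p = 0.795). All 16 measured genes of T cells and cytotoxic lymphocytes rose, also adjusted over the list alone, with a median of 6.74. They included Cd5 (6.29), the pore-forming protein Prf1 (7.12) and the kinase Lck (1.93). All 3 measured natural killer cell genes rose, Klrd1 by 7.18, Klrk1 by 6.68 and Eomes by 2.57, also adjusted over the list alone. Only these 3 of the 7 listed genes passed the filter, so the list alone does not show more natural killer cell RNA. Of 14 macrophage and monocyte genes 11 rose, 13 adjusted over the list alone, with a median of 4.39, among them Ly6c2 (6.85), the chemokine receptor Ccr2 (5.86), Adgre1 (4.97), which encodes F4/80, and Cd68 (3.11). Of 7 dendritic cell genes 6 rose, also adjusted over the list alone, with a median of 3.67, including Xcr1 (5.18), Itgax (5.53), Batf3 (2.50) and Fscn1 (0.69). Of 3 measured B cell and plasma cell genes 2 rose, the immunoglobulin genes Ighm (5.47) and Igkc (3.45), and 3 did so adjusted over the list alone (median 3.45). Of 5 neutrophil genes 3 rose, 4 adjusted over the list alone, with a median of 3.40: the receptor Csf3r (5.92), the collagenase Mmp8 (4.65) and the calcium-binding protein S100a9 (3.40). None of the 7 genes of mast cells and basophils passed the filter, so they were not tested.

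The camera adjusted p of these lists was 2.36e-05 for leukocytes (adjusted p = 0.305 with an estimated correlation), 2.36e-10 for T cells and cytotoxic lymphocytes (adjusted p = 0.274 with an estimated correlation) and 0.00819 for natural killer cells (adjusted p = 0.274 with an estimated correlation). It was 6.43e-07 for macrophages and monocytes and 0.00242 for dendritic cells (for both, adjusted p = 0.305 with an estimated correlation). For B cells and plasma cells it was 0.0473 (adjusted p = 0.305 with an estimated correlation) and for neutrophils 0.0314 (adjusted p = 0.366 with an estimated correlation). With the leukocyte score as covariate, 4 of 16 T cell genes stayed higher (median 1.22) and the calls of the other 6 lists ended, that of the leukocyte list by construction. The list B cells and plasma cells lost its call without Ctrl 2 (0.0550), iKO 2 (0.0822), iKO 3 (0.0724), iKO 4 (0.0986) or iKO 6 (0.0531), and S100a9 (edgeR, adjusted p = 0.0365) lost its own without any 1 of Ctrl 1, 2, 3, 4 or 6 or iKO 3 to 6 (0.0503 to 0.0765). Log2 fold changes were larger without Ctrl 5: Rac2 7.70, Prf1 8.23, Klrk1 9.93, Ighm 7.84, Igkc 4.21, Ly6c2 9.36, Ccr2 8.65, Adgre1 7.57, Xcr1 6.99, Itgax 7.68, Csf3r 8.87 and S100a9 5.99. Cd5, Klrd1 and Mmp8 had 2, 3 and 2 Ctrl counts there, with count ratios of 294 (95% counting interval 81.0 to 2434), 531 (181 to 2578) and 299 (82.3 to 2473). With limma voom the calls of Prf1 (adjusted p = 0.0570), Ly6c2 (0.0880), Ccr2 (0.0996), Csf3r (0.0677), Mmp8 (0.0764) and Itgax (0.0571) were lost.

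Genes of immune signalling rose with the leukocyte score. All 9 measured MHC class II genes rose, also adjusted over the list alone, with a median of 4.07: H2-Aa went from 15.2 ± 13.5 to 258 ± 114 CPM (SD, n = 6, log2 fold change 4.09, and 4.76 without Ctrl 5), the transactivator Ciita rose by 3.36, and H2-DMa and H2-DMb1, which load peptides, by 3.27 and 2.32. Of 20 chemokine genes 16 rose, 17 adjusted over the list alone, with a median of 3.66, among them the ligands of CXCR3 Cxcl9 (4.53) and Cxcl10 (2.20) and the T cell attractant Ccl5 (2.64). Cxcl11 rose too (2.50) but is annotated as a polymorphic pseudogene. Of the exon bases of Cxcl11 41.7% are shared with Gm2673. Of 18 genes of the NF-kB and TNF response 17 rose, also adjusted over the list alone, with a median of 1.79, including Birc3 (2.11), an inhibitor of apoptosis, the NF-kB subunits Relb (0.73) and Nfkb2 (0.70), and Tnfaip2 (0.55). Of 12 immune checkpoint ligands 10 rose, also adjusted over the list alone, with a median of 2.33. Cd274, which encodes PD-L1, went from 25.1 ± 1.89 to 164 ± 36.8 CPM (SD, n = 6, log2 fold change 2.71), Tnfrsf14 rose by 2.58, Cd47, a signal against phagocytosis, by 1.33 and Lgals9 by 1.12. The camera adjusted p was 9.32e-07 for MHC class II, 2.13e-07 for chemokines, 2.32e-08 for NF-kB and 1.30e-05 for checkpoint ligands, and for each of the 4 lists adjusted p = 0.274 with an estimated correlation. The 4 calls ended with the leukocyte score as covariate: camera adjusted p = 0.0962 for the list MHC class II antigen presentation, 0.122 for the list chemokines, 0.112 for the list NF-kB and TNF response and 0.0556 for the list immune checkpoint ligands. There 0, 3, 1 and 2 of their genes were higher.

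Genes of proliferation, respiration and translation were modestly lower in iKO. Of 30 cell cycle genes 29 fell, also adjusted over the list alone, with a median of -0.57. Cdk1, the kinase that drives mitosis, went from 148 ± 6.27 to 73.7 ± 8.56 CPM (SD, n = 6, log2 fold change -1.0 ± 0.07), its cyclin Ccnb1 changed by -1.04, and Rrm2 and Tyms, which make DNA precursors, by -0.80 and -0.71. Mki67, the member that did not pass, named after its value was seen, had a log2 fold change of 0.081 (edgeR, adjusted p = 0.612). Of 26 oxidative phosphorylation genes 24 fell, also adjusted over the list alone, with a median of -0.35, including the complex I genes Ndufa5 (-0.73), Ndufs1 (-0.46) and Ndufb5 (-0.54), and Ndufa4 (-0.73). Of 30 ribosomal protein genes 29 fell, 30 adjusted over the list alone, with a median of -0.33 and like values for Rpl8 (-0.43), Rpl7 (-0.34) and Rps4x (-0.37). Camera adjusted p was 6.00e-16 for the cell cycle (adjusted p = 0.262 with an estimated correlation), 1.58e-09 for oxidative phosphorylation (adjusted p = 0.305 with an estimated correlation) and 6.60e-08 for ribosomal proteins (adjusted p = 0.366 with an estimated correlation). With the leukocyte score as covariate, 21, 21 and 26 members were lower, with medians of -0.70, -0.58 and -0.65. Ctrl 5 and Ctrl 4, highest in leukocyte score among Ctrl (4.41 and 2.02), also had the highest ribosomal scores (9.95 and 9.80). The same held for oxidative phosphorylation (7.77 and 7.68), so the larger medians of these lists do not show falls apart from leukocyte content. Ribosomal scores overlapped between the groups (9.51 in Ctrl 1, 9.56 in iKO 6).

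Genes of cholesterol synthesis, of the stress response to unfolded protein and of pigment cells were lower too, beside the higher leukocyte score. Of 20 cholesterol synthesis genes 16 fell, also adjusted over the list alone, with a median of -0.40, among them Hmgcs1 (-0.52), Msmo1 (-0.57), Mvd (-0.46) and Fdft1 (-0.40), all enzymes of the pathway. Of 20 genes of the unfolded protein and integrated stress response 14 fell and 2 rose, also adjusted over the list alone, with a median of -0.45. Atf4, a transcription factor of that response, changed by -0.45, the mitochondrial folate enzyme Mthfd2 by -0.62 and the chaperone component Sdf2l1 by -0.72. The 2 that rose were Atf3 (1.5) and, named after its value was seen, Ppp1r15a (0.28). Of 20 pigment cell genes 12 fell, 13 adjusted over the list alone, 1 rose and 7 did not pass, with a median of -0.31. Tyrp1, an enzyme of melanin synthesis, went from 6655 ± 365 to 5220.2 ± 488 CPM (SD, n = 6), and Mitf, the transcription factor of melanocytes, Rab38, which serves the transport of melanin enzymes, and Cdk2 changed by -0.44, -0.37 and -0.27. Gpnmb, a melanosome glycoprotein named after its value was seen, rose by 0.29. The camera adjusted p was 3.25e-07 for cholesterol synthesis (adjusted p = 0.274 with an estimated correlation), and 0.000721 for the stress response and 0.00312 for pigment cells (for both, adjusted p = 0.366 with an estimated correlation). With the leukocyte score as covariate the 3 calls ended (camera adjusted p = 0.122, 0.307 and 0.856), with 2, 1 and 0 members lower.

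Stromal and skin transcripts varied strongly among the iKO libraries. Fibroblast scores lay between 4.98 and 5.03 in Ctrl and were 7.80 in iKO 2, 7.25 in iKO 5, 3.24 in iKO 6 and 5.15 to 5.43 in the other iKO libraries. Of 13 fibroblast genes 4 rose, 2 adjusted over the list alone, namely Thy1 (1.75), Pdgfrb (1.20), Cd34 (1.95) and Pi16 (2.07), and the list did not pass (median 1.26, camera adjusted p = 0.173, and 0.00392 without iKO 6). Of 25 genes of collagen and extracellular matrix 8 rose, 4 adjusted over the list alone, with a median of 1.26, among them Thbs1 (2.09), Fn1 (1.77), which encodes fibronectin, Mmp14 (0.27) and Col6a3 (1.82, and 1.23 without iKO 2). The list collagen and extracellular matrix passed with camera (camera adjusted p = 0.0342; adjusted p = 0.649 with an estimated correlation) but not without Ctrl 2 (0.0786), Ctrl 3 (0.0636), Ctrl 4 (0.0714), Ctrl 5 (0.0921), iKO 2 (0.195) or iKO 5 (0.125). Its median was -0.014 without iKO replicates 2 and 5, an omission chosen after the data were seen. Its score did not pass (exact permutation test, adjusted p = 0.290, and 0.00392 without iKO 6). Its call also ended with the leukocyte score as covariate (0.175) and with fry (0.195). The call of Cd34 (edgeR, adjusted p = 0.0415) was lost without any 1 Ctrl library, iKO 2 or iKO 5 (0.0583 to 0.107), and that of Pi16 (0.0442) without any 1 Ctrl library, iKO 1, iKO 2 or iKO 5 (0.0503 to 0.108). All 10 measured complement genes rose, also adjusted over the list alone, with a median of 2.29 (camera adjusted p = 0.000125; adjusted p = 0.305 with an estimated correlation), among them C4b (1.94), C2 (0.65) and Cfb (2.51). Of the exon bases of Cfb 79.5% and of those of C2 46.9% are shared with other genes. Without iKO replicates 2 and 5, 7 of the 10 were higher, with a median of 1.04. Across the 6 iKO libraries the complement score followed the fibroblast score (Pearson r = 0.97, exact permutation p = 0.00139, adjusted 0.0111; Spearman rho = 1.00, exact p = 0.00278, adjusted 0.0222; 8 relations computed), and r was 0.996 without the 2 libraries farthest from the median fibroblast score. That 0.996 rests on iKO 5 (fibroblast score 7.25, complement score 6.02), since iKO 1, 3 and 4 lay close together (5.15 to 5.43 and 4.31 to 4.59). Within Ctrl r was 0.82 (exact permutation p = 0.0444, adjusted 0.178) and rho 0.83 (exact p = 0.0583, adjusted 0.233), and r without the 2 farthest libraries was 0.11.

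All 9 measured keratinocyte and skin epithelium genes rose, also adjusted over the list alone, with a median of 3.49, and iKO 2 set much of the size. Its keratinocyte score was 4.96, against -0.12 to 1.46 in the other iKO libraries and -0.45 to -0.28 in Ctrl. The keratins Krt14 and Krt5, the desmosome protein Dsp and Sfn rose by 4.05, 3.82, 2.96 and 1.25, and by 2.06, 1.62, 1.14 and 0.61 without iKO 2. The list keratinocytes and skin epithelium passed (camera adjusted p = 0.0473; adjusted p = 0.571 with an estimated correlation), but not without any 1 of the Ctrl libraries, iKO 1 or iKO 3 (0.0569 to 0.0956), with fry (0.0695) or with the leukocyte score as covariate (0.122). All 3 measured adipocyte genes rose, also adjusted over the list alone, with a median of 3.61: Lpl (3.61), a lipase, Pparg (4.28), a nuclear receptor, and Fabp4 (1.19), a fatty acid carrier (camera adjusted p = 0.0267, and 0.858 for the list adipocytes with the leukocyte score as covariate; adjusted p = 0.324 with an estimated correlation). Only these 3 of the 9 listed adipocyte genes passed the filter. The adipocyte score was 2.45 in Ctrl 5 and 1.78 in iKO 1, between the other Ctrl and the other iKO libraries, as was the leukocyte score. The cells in which these genes rose are therefore not known. Of 9 pericyte and smooth muscle genes 6 rose, also adjusted over the list alone, including Notch3 (1.32), Abcc9 (1.62), Myh11 (1.22) and Rgs5 (1.43), but the list did not pass with camera (median 1.22, camera adjusted p = 0.108, and 0.0443 without iKO 4). It passed with fry (adjusted p = 0.0285), and its score rose by 0.70 (exact permutation test, adjusted p = 0.0324), a call lost without any 1 of Ctrl 1, 2, 4 or 6 or iKO 2 or 5 (0.0540 to 0.0648). Of 8 skeletal muscle genes 6 rose, 7 adjusted over the list alone, including Atp2a1 (1.97), Tnnt3 (3.07), Acta1 (2.24, and 1.604 without iKO 2) and Myl1 (2.56, and 1.88 without iKO 2), with no call for the list skeletal muscle (median 2.26, camera adjusted p = 0.127, and 0.0496 without iKO 3). The call of Acta1 (edgeR, adjusted p = 0.0267) was lost without Ctrl 5, Ctrl 6, iKO 2 or iKO 5 (0.0518 to 0.0643) and that of Myl1 (0.0382) without Ctrl 1, 2, 4, 5 or 6, iKO 2 or iKO 5 (0.0601 to 0.0955).

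Of 12 endothelial genes 5 rose and 1 fell, also adjusted over the list alone, with no call for the list from camera (median 0.26, camera adjusted p = 0.275) or fry (adjusted p = 0.0695). Its score rose by 0.64 (exact permutation test, adjusted p = 0.0165), without a call when members were standardised (0.109). The VEGF receptors Kdr and Flt1 rose by 2.54 and 2.32, and Egfl7, which endothelial cells secrete, changed by -0.73. Of 8 Schwann cell and nerve genes 3 rose and 1 fell, 3 and 2 adjusted over the list alone, with no camera call for the list (median 0.25, camera adjusted p = 0.513), but one with fry (adjusted p = 0.0140). Its score rose by 0.57 (exact permutation test, adjusted p = 0.00411), without a call when members were standardised (0.167). Egr2, a transcription factor, rose by 2.92, the myelin gene Pmp22 by 1.52 and Prx by 0.62, and S100b changed by -0.50. The call of Prx (edgeR, adjusted p = 0.0380) was lost without Ctrl 1, 2, 3, 5 or 6 or iKO 2, 3, 4 or 6 (0.0524 to 0.0798). None of the 3 measured erythroid genes passed with edgeR, at an unadjusted p under 0.05 or adjusted over the list alone, and the globin genes Hbb-bs and Hba-a1 had log2 fold changes of 1.06 (adjusted p = 0.253) and 0.93 (0.384), with camera adjusted p = 0.744 for the list.

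Of 16 genes marking dedifferentiated melanoma 9 rose, 11 adjusted over the list alone, with a median of 1.02 (camera adjusted p = 0.00557; adjusted p = 0.366 with an estimated correlation), including the receptor kinase Axl (2.27), the transcription factor Zeb1 (2.04), the ectoenzyme Nt5e (2.38) and Wnt5a (2.37, and 1.62 without iKO 2). The score of this list was highest in iKO 2 (4.11) and iKO 5 (3.58) and, among iKO, lowest in iKO 6 (2.32), as was the fibroblast score. The median was 0.45 with the fibroblast score as covariate (7 higher, camera adjusted p = 0.0116) and 0.44 without iKO replicates 2 and 5 (5 higher, 0.0461), so the cells in which these genes rose are not known. Of 15 TGF-beta response genes 7 rose, also adjusted over the list alone, with a median of 0.44 (camera adjusted p = 0.0204, 0.0766 without iKO 2 and 0.135 without iKO replicates 2 and 5; adjusted p = 0.311 with an estimated correlation), among them Inhba (2.38), Smad7 (0.81), Tgfb1 (1.32) and Skil (0.84). Of 17 immediate early and heat shock genes, which tissue dissociation can raise, 11 rose and 1 fell, also adjusted over the list alone, with a median of 0.47 (camera adjusted p = 0.000765; adjusted p = 0.326 with an estimated correlation). Socs3, Junb and Dusp1 rose by 1.32, 1.11 and 2.07, and Hsp90aa1, named after its value was seen, changed by -0.43. These 3 calls ended with the leukocyte score as covariate (camera adjusted p = 0.0556 for the list dedifferentiated melanoma, 0.122 for the list TGF-beta response and 0.818 for the dissociation genes). Of 20 genes in the list hypoxia and glycolysis 8 rose and 2 fell, also adjusted over the list alone, with a median of 0.20 and no camera call (adjusted p = 0.0685, 0.00706 without iKO 1 and 0.0381 without iKO 2), while their score rose by 0.33 (exact permutation test, adjusted p = 0.0308). That call was lost when members were standardised (0.167), with the replicate block (0.0720) and without any 1 of Ctrl 1, Ctrl 6, iKO 4, iKO 5 or iKO 6 (0.0514 to 0.0598). Pfkfb4, Egln3, Pfkfb3 and Kdm3a rose by 1.18, 1.51, 1.45 and 0.38. The 19 p53 target genes went both ways, with 6 higher and 8 lower, also adjusted over the list alone. Their median log2 fold change was -0.047 and camera put them lower without a call (adjusted p = 0.499), whereas their mean was 0.54 and their score rose by 0.44 (exact permutation test, adjusted p = 0.00851). With standardised members the score turned to -0.16 (adjusted p = 0.159), so no common direction is shown. Btg2 and Plk2 rose by 2.21 and 0.89, and Ccng1 and Ei24 changed by -0.69 and -0.41. Of 13 mitochondrially encoded transcripts 1 rose, also adjusted over the list alone, mt-Co1 (0.61), with no call for the list (median 0.12, camera adjusted p = 0.488).

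**Figure D4:**
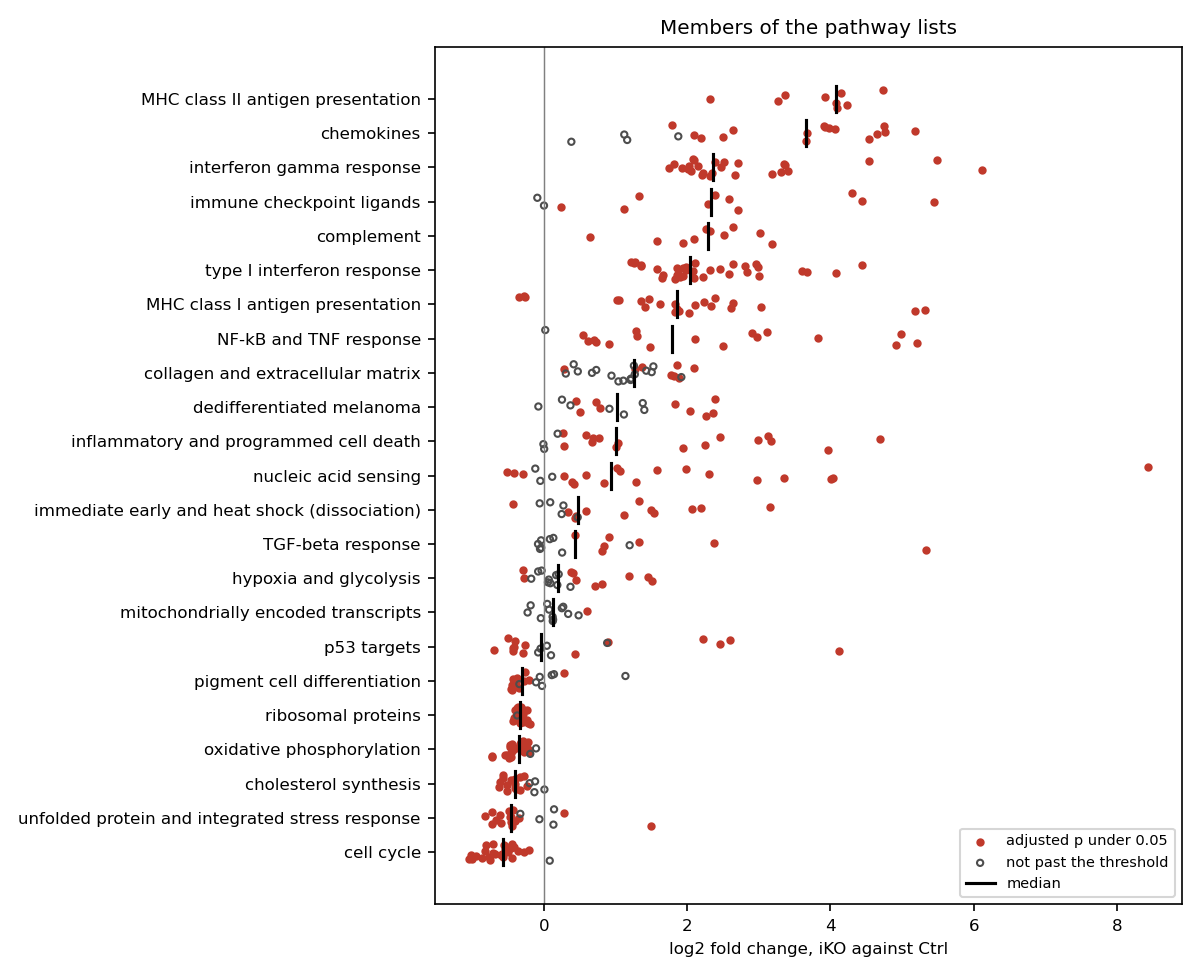
Each point is the log2 fold change (iKO over Ctrl) of a measured member of a pathway list, filled red where the edgeR adjusted p was under 0.05 and open otherwise, with a black tick at the list median. All 34 type I interferon genes lie above 0 and 29 of 30 cell cycle genes below it past the threshold.

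Of 38 tested lists 29 passed with camera at the preset correlation, 23 higher and 6 lower. With an estimated correlation 0 passed (camera, adjusted p from 0.262 to 0.842), and 6 had an unadjusted p under 0.05, while 29 passed with fry and 10 with the leukocyte score as covariate. List scores differed in 33 lists by the exact permutation test, 27 higher and 6 lower.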

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

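The look at Xist was chosen after the result was seen, and that at the other values before. A value was singled out where the highest or lowest of the 6 libraries in a group lay far from the other 5, by a gap to the nearest that exceeded Dixon's 95% critical share of the group's range. This met 90 of 398 groups of values, where chance gives about 1 in 20, or 19.9, and the values are not independent because lists and genes overlap. Ctrl 5 held 33 of the 90, and most of the other 57 were in iKO 1. No biological explanation was tested for the position of these single libraries.

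Ctrl 5 stood apart from the other Ctrl libraries in 12 list scores (mean log2 CPM): type I interferon response 4.67, MHC class I 6.34, MHC class II 4.26, chemokines 2.41, NF-kB and TNF response 3.47, immune checkpoint ligands 3.58, immediate early and heat shock 6.62, T cells and cytotoxic lymphocytes -0.48, natural killer cells -0.94, neutrophils 0.46, dendritic cells 1.41 and adipocytes 2.45, each above the other Ctrl libraries. Among genes (log2 CPM) it was apart and higher for Ipcef1 -3.19, Ms4a8a -3.19, Cd8b1 -1.37, H2-DMa 3.21, H2-Aa 5.42, Atf3 5.80, Thbs1 5.72, Mmp14 8.31, Junb 7.35, Dusp1 6.36, Lcp1 6.13, Rac2 2.43, Prf1 0.067, Klrk1 0.37, Cd68 5.31, Mmp8 -0.48, Fscn1 4.80 and Lpl 5.09. For Ipcef1, Ms4a8a and Cd8b1 the 5 other Ctrl libraries had 0 counts, so that any count in Ctrl 5 would set it apart, and these 3 carry no weight in the count of 33. It was apart and lower for Mitf 9.48, Wnt5a -1.86 and Cfb -2.38.

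The library iKO 1 stood apart below the other iKO libraries in 13 list scores (mean log2 CPM): type I interferon response 6.18, MHC class II 4.36, nucleic acid sensing 5.14, NF-kB and TNF response 3.56, immune checkpoint ligands 3.86, cell death 4.26, leukocytes 4.11, T cells and cytotoxic lymphocytes 0.21, natural killer cells -0.35, macrophages and monocytes 4.43, neutrophils -2.13, dendritic cells 0.54 and adipocytes 1.78. Genes (log2 CPM) in which it was lowest and apart were Ptprc 4.12, Pecam1 1.98, Ctla4 0.21, Ipcef1 -0.81, Tlr9 1.00, Ms4a8a 0.034, Cd244a -0.16, Cd8b1 0.53, Parp14 7.62, H2-DMb1 4.57, H2-DMa 3.83, H2-Aa 5.50, Cxcl11 1.06, Cd274 6.56, Cd47 6.41, Tnfrsf14 2.28, Egln3 2.68 and Thbs1 5.60. So were Ptpn6 5.57, Rac2 2.84, Cd5 -1.40, Prf1 1.64, Klrd1 -1.18, Klrk1 0.71, Cd68 4.95, Ly6c2 2.81, Ccr2 2.45, Adgre1 3.97, Csf3r 0.43, Mmp8 -4.19, S100a9 -2.72, Itgax 1.57, Kdr 1.5, Flt1 2.08 and Pparg -0.73.

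The library iKO 2 stood above the other iKO libraries in the keratinocyte score (4.96) and in Krt14 (5.46), Krt5 (6.54), Sfn (4.86) and Dsp (5.94 log2 CPM). Rlbp1 was lowest and apart in iKO 5 (-0.34) and Egfl7 in iKO 4 (1.74), and Cxcl11 was lowest and apart in Ctrl 6 (-1.23). Xist in Ctrl 3 (0.501 CPM) stood above the other Ctrl libraries (0.0428 to 0.166 CPM).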

How the results depend on the processing

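The runs without iKO 2 and 3, without iKO 2 and 5 and with thinned counts were chosen after the result was seen. Of 152 named genes 47 kept direction and call under every alternative that could test them, the fold change threshold of 1 not being applied to single named genes, and 125 did so leaving aside the leukocyte score as covariate; of 38 lists, 1 and 27 did so (leaving aside also the estimated correlation for lists). DESeq2 size factors, total counts without a composition factor, the DESeq2 Wald test and thinning changed no call or direction among the named genes they could test (152, 152, 148 and 149). Requiring at least 1 CPM in 6 libraries left 135 of the 152 genes and 35 lists to test, and thinning 37 lists. The calls of the list B cells and plasma cells (adjusted p 0.0519, 0.0546 and 0.0516) and the list keratinocytes and skin epithelium (0.0519, 0.0507 and 0.0595) were lost with DESeq2 size factors, a prior count of 0.5 and thinning. The CPM filter ended those of the list neutrophils (0.0691) and of keratinocytes (0.0794). The fibroblast score as covariate ended those of collagen (0.724), B cells (0.0520) and keratinocytes (0.103). Of 152 named genes limma voom ended the calls of 16, the 6 leukocyte genes given above and Col6a3, Cd34, Pi16, Krt14, Krt5, Sfn, Dsp, Tnnt3, Acta1 and Myl1 (0.0519 to 0.338). Sample weights ended 6 (Cd34, Pi16, Krt5, Dsp, Acta1 and Myl1), the fibroblast score 6 (Nxf3, Bcan, S100a9, Pi16, Dsp and Myl1), and no filter 10 (Nxf3, Bcan, S100a9, Fscn1, Cd34, Pi16, Sfn, Acta1, Myl1 and Prx). Leaving out iKO 2 and 3 ended 6 calls of named genes and 5 of lists, and leaving out iKO 2 and 5 ended 14 and 4, that of collagen with its direction. With total counts 49.9% of calls were higher against 53.8%. No alternative gave a value for Trex1. The counts of genes moved by over 1.5 times with the leukocyte score as covariate (1095 higher, 1179 lower) and with an absolute log2 fold change of at least 1 (1891 and 95), the latter because it adds a condition. Lists past the threshold fell from 29 to 10 with that covariate and to 0 with an estimated correlation (camera; 6 at an unadjusted p under 0.05, and 29 with fry). The cause was not tested, except that the covariate nearly follows the groups. With the leukocyte score as covariate the log2 fold changes of Pecam1 (-0.023), Igkc (-0.46), Ccr2 (-0.22), Csf3r (-0.035), Mmp8 (-2.66), S100a9 (-2.62), Itgax (-0.076), Fscn1 (-0.19), Fabp4 (-0.63), Prx (-0.11), Hbb-bs (-2.16) and Hba-a1 (-3.43) turned negative, as did Hba-a1 with limma voom (-0.20). List directions turned with it for hypoxia (adjusted p 0.122), mitochondrial transcripts (0.248), leukocytes (0.856), macrophages (0.248), neutrophils (0.175), dendritic cells (0.658), endothelial cells (0.669), adipocytes (0.858) and erythroid cells (0.122). That of the leukocyte list is fixed by the covariate, as is that of the fibroblast list below. With the fibroblast score as covariate the fibroblast list turned (0.299), and without iKO replicates 2 and 5 the list collagen and extracellular matrix (0.636), the list mitochondrially encoded transcripts (0.966) and the list fibroblasts (0.596). Leaving out each library gave 3707 to 4484 genes higher, 2671 to 3750 lower, 26 to 29 lists and 31 to 34 list scores. Among scores, with standardised members that of p53 targets turned (-0.16, adjusted p 0.159) and those of hypoxia (0.167), endothelial (0.109) and Schwann cells (0.167) lost their call. Without iKO replicates 2 and 5 the collagen (-0.072, 0.943) and fibroblast scores (-0.20, 0.890) turned. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.13 to 0.25, 2 of 6 above 0.1, and 1 of 6 Ctrl libraries matched its own number best. The replicate block ended 10 calls of named genes, Nxf3, Bcan, Col6a3, Cd34, Pi16, Krt5, Tnnt3, Acta1, Myl1 and Prx (adjusted p 0.0540 to 0.301). With the replicate block 3489 genes were higher and 2984 lower (3436 and 2932 of them without it too), 29 lists passed, and 30 scores passed a sign-flip test, with the calls of hypoxia, stress response and pericyte scores lost (adjusted p 0.0720 each). Depth limits fold changes of genes at or near 0 counts in Ctrl, which are bounds or wide intervals.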

Other observations

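The lists in the first 3 paragraphs were chosen after the data were seen, as were the tests of Xist, of dilution, of equal depth and of the runs without iKO 2 and 3. The p-values of these added lists were adjusted over the added lists alone, and their calls carry less weight than those of the fixed lists. Transcripts of T cell inhibitory receptors were higher in iKO: 6 of 6 measured genes rose, with a median log2 fold change of 4.25, among them Pdcd1 (PD-1, 6.93), Tigit (5.53), Havcr2 (4.20) and Lag3 (3.26). All 27 Ctrl counts of Pdcd1 and all 27 of Il2ra were in Ctrl 5, so their fold changes rest on it. All 4 measured regulatory T cell genes rose too (median 2.93), including Il2ra (5.27). Camera adjusted p was 0.000142 and 0.00360 (adjusted p = 0.128 for both with an estimated correlation). All 16 genes of the T cell list rose with them, by a larger median of 6.74, so these values do not show a rise beyond that of T cell RNA. Ifng, which encodes interferon gamma, went from 14 counts, all in Ctrl 5, to 949 in iKO, and 25.95% of its exon bases are shared with Gm49751. Ifnb1, which encodes interferon beta, had 2 counts in Ctrl, both in Ctrl 5, and 122 in iKO (6 to 52 per library), too few for the filter.

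Genes of opposite macrophage states were both higher, beside a general macrophage and monocyte list that rose by a median of 4.39. Its score was 5.04 in Ctrl 5, 1.96 in Ctrl 4 and -0.69 to -0.21 in the other Ctrl libraries against a mean of 6.77 in iKO, a difference of 5.84, and 6.68 without Ctrl 5. All 7 measured genes of activation by interferon rose (median 5.28), including Nos2 (5.64) and Acod1 (6.81), which make nitric oxide and itaconate, and 8 of 9 genes of alternative activation rose (median 3.47), including Arg1 (4.94) and Chil3 (5.55). Cd163 did not pass (2.42, edgeR, adjusted p = 0.108). Camera adjusted p was 4.96e-05 and 0.000142 (adjusted p = 0.128 and 0.153 with an estimated correlation). A change of state beyond more macrophage RNA was not tested.

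Of 7 genes of cartilage-type matrix 4 fell and none rose past the threshold, with a median of -0.62: Col2a1 (-1.48), Col9a2 (-1.38), Scrg1 (-1.38) and Col11a2 (-0.42), while Comp was at 1.32 (edgeR, adjusted p = 0.211). Camera adjusted p was 0.00724 (adjusted p = 0.128 with an estimated correlation). Gkn3 counts were 115 to 197 per Ctrl library and 0 to 6 per iKO library, and Tex19.1 counts 22 to 72 and 0 to 8. Of the germ line list 1 gene was measured, Ddx4 (0.60, edgeR, adjusted p = 0.244).

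All 34 type I interferon genes were higher in iKO. Leukocyte RNA as the whole cause is argued against by the 33 that stayed higher with the leukocyte score as covariate, at a median of 1.601 against 2.03. The 2 libraries with Xist are argued against by the 34 that stayed higher without iKO 2 and 3 (median 1.98). The covariate nearly follows the groups and rests on Ctrl 5 and iKO 1, so part of the rise may come from infiltrating cells. Loss of host Trex1 and interferon made by infiltrating cells stay open as hypotheses, not tested further.

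Xist was high and Y-linked counts were almost absent in iKO 2 and 3. Loss of Y-linked expression by tumour cells alone is argued against by Xist, whose lower value there (117 CPM) was 233 times the highest Ctrl library (0.501 CPM). Hosts of the other sex than the label's stay open: the Y-linked count per 100 Ptprc counts, at most 0.884 in the 2 and at least 14.9 in the other iKO libraries, restates the pattern and decides nothing. Ctrl 3 had 107 Y-linked counts beside 6 of Ptprc, so the 0 in iKO 3 does not follow from the sex of host leukocytes alone. Which cells gave the counts in Ctrl 3 is not known, so they do not argue against hosts of the other sex. A mislabelled or mixed sample stays open too, as does Xist at 8.39 CPM in iKO 4.

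The cell cycle list was lower in iKO. Dilution of tumour RNA by other cells as the whole cause is argued against by the cell cycle score minus the pigment cell score, -1.77 in Ctrl and -2.19 in iKO, a difference of -0.42 (exact permutation p = 0.00216, the smallest possible). The pigment members, however, reached up to 1.14, with a mean log2 fold change of -0.16 and a median of -0.31. Part of the -0.42 thus comes from members that did not fall, and the list medians (-0.57 and -0.31) lie closer together. With the leukocyte score as covariate 21 of 30 members stayed lower (median -0.70 against -0.57). That covariate nearly follows the groups and rests mainly on Ctrl 5 and iKO 1, so it cannot decide whether leukocyte content was a cause. At leukocyte scores of 4.41 and 4.11, the cell cycle score was 6.95 in Ctrl 5 and 6.21 in iKO 1, but these are single libraries. Shallower iKO libraries are argued against by the 29 members that stayed lower after thinning (median -0.55). Slower division of tumour cells may contribute but was not tested, and a change in the pigment genes themselves stays open.

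The 12 libraries can be split in 462 ways, of which 100 with the real one were compared. For the 4037 genes higher and the 3464 lower in iKO, 1 of 100 splits, the real one, gave as many in 1 direction (highest other 2633 for each). That other split kept 5 libraries of 1 group together. A split that mixes the groups places their difference in the spread within each side, which leaves few or no calls. Libraries may also share mice, so this count does not exclude chance. For the 29 gene lists 14 of 100 splits gave as many, and the highest other gave 34. Each other split with as many kept 4 or 5 libraries of 1 group together, and so part of the group difference. The 14 are thus no measure of chance, which is not excluded. Splits with 3 libraries of each group on each side gave up to 21 lists. The number of lists called by camera at the preset correlation is therefore no evidence of a group difference by itself.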
